A study of Mus musculus with 8 samples.

How the data were processed

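Total RNA of round spermatids, the haploid germ cells that follow meiosis, was measured on Illumina mouse bead arrays. The cells came from the testes of mice aged 8 weeks and were separated by centrifugal elutriation, per the labels' protocols. The 8 arrays fell into 3 groups: 4 wildtype arrays, 2 arrays labelled with a transgene against the X-linked Slx genes (shSLX) and 2 labelled with a transgene against the Y-linked Sly genes (shSLY). Both transgenes express short hairpin RNAs, which lower target transcripts by RNA interference. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The array labels place the arrays on 3 slides. The first held wildtype 2, the second held wildtype 1 with both shSLY arrays, and the third held wildtype 3 and 4 with both shSLX arrays.

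Both deposited tables hold probe intensity on a linear scale for 45281 probes. The first deposited table gives non-normalized intensity and a detection p-value for each array, per the file headers. The second, the series matrix, gives intensity values that the authors had normalized: its minimum of 46.4 and maximum of 42689 are the same on all 8 arrays, and the array medians lie between 73.6 and 73.7. That pattern is the one quantile normalization leaves, and whether the background was subtracted is not given in the sources used here. BeadStudio and GenomeStudio are named in the submitters' processing notes, without versions. All values were positive and on a linear scale.

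The 2 tables disagree over which array is which. The column headers of the non-normalized table are array labels and the columns of the series matrix are sample accessions, and the sample records tie each array label to an accession. Over all probes, the ranks of 2 of the 8 non-normalized columns (wildtype 1 and 2) were those of the series matrix column of the same sample, with a Spearman correlation of 1. The ranks of 4 columns were those of another sample: the columns headed wildtype 3 and 4 held the ranks of shSLY 1 and 2, and the columns headed shSLY 1 and 2 held those of shSLX 1 and 2. The 2 columns headed shSLX 1 and 2 matched no series matrix column, with best correlations of 0.893 and 0.916. The series matrix values of wildtype 3 and 4 had no partner in the non-normalized table. Nothing in the sources used here settles which table carries the right names.

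The design fixed before the data were examined took the non-normalized table with limma's neqc as the main source and the series matrix as an alternative. These roles were exchanged after both tables had been examined, including the X and Y pattern and the Sly values, because the accession is the identity the sample records use. The results therefore rest on the series matrix, named by accession, and the fit first planned is given as an alternative under its own headers. In that alternative, the columns headed wildtype 3 and 4 hold the ranks of shSLY 1 and 2, and those headed shSLY the ranks of shSLX 1 and 2. This exchange of names can by itself turn a direction, so the alternative is not a check on separate measurements. No column was renamed by its values. The slides too come from the array labels, whose tie to the accessions is what the tables dispute.

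Series matrix values were background-corrected with limma's normexp model (offset 50), quantile-normalized and converted to log2. Probes were kept where the deposited detection p-value was under 0.01 in at least 2 of the 8 columns of the non-normalized table, a rule that needs no column identity, although 2 of those columns match none in the series matrix. This left 16572 probes. Between 13572 and 16113 probes were detected per column. Group and slide were fitted together with lmFit and eBayes (limma 3.58.1 in R 4.3.3) over all 8 arrays, with 3 residual and 5.69 prior degrees of freedom. With the slide term, the shSLX arrays were in effect set against 2 wildtype arrays and the shSLY arrays against 1, and the number of arrays limits the precision. Every adjusted p for a probe is limma's, adjusted by Benjamini-Hochberg over the 16572 probes, with a threshold of 0.05. The difference between the 2 knockdown effects was tested as a contrast in the same fit.

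Probe names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of the named probes, 34807 were updated through their gene identifiers to the GRCm38.p6 gene table. That table was used for names, chromosomes and gene order, and no coordinates are given because the files name no genome build. For gene groups, 1 probe per gene was used, the one with the highest mean, giving 9451 genes. The 22 gene lists were fixed before the data were examined. Lists were tested with camera (limma, two-sided) at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 22 lists. Limma's fry, which asks whether a list changed without setting it against other genes, was run beside it. Its p-values are given unadjusted. X and Y genes were tested in the same way and adjusted over the 2 chromosomes. The X and Y medians were also set against 10000 random autosomal lists of the same size matched on mean signal.

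Genes were named by a rule fixed in advance. It took every probe of Slx, Slxl1 and Sly. For each knockdown it took up to 12 genes with the largest rise and 12 with the largest fall among probes past the threshold. Those probes needed 1 symbol that is not a bare clone identifier and values on the shared slide that do not overlap. For each list it took up to 4 members past the threshold, or else the 2 with the smallest p. It also took the 6 genes with the smallest adjusted p for the difference between effects. Genes named outside the rule are marked as chosen after their values were seen.

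The fit was tested on simulated data, with 50 probes changed at each size in each comparison among 16572 probes and spreads drawn from the fitted prior. A log2 change of 1 was called for 90.0% of the changed probes in the shSLX comparison and 92.0% in the shSLY comparison. A change of 0.5 was called for 10.0% and 8.0%. Of the calls, 7.98% and 6.29% were probes that had not been changed. Alternatives covered background correction, the offset, normalization, the filter on dim probes, the slide as a fixed or random block or left out, single-slide fits, the replicate number as a block, 1 probe per gene, and each array left out in turn. A filter on detection in all arrays of a group was planned but not run, since it needs the disputed column identities. Figures were drawn with matplotlib 3.10.9.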

Results

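The data set comprised 8 array profiles of purified round spermatids: 4 wildtype, 2 labelled shSLX and 2 labelled shSLY. Slx and Slxl1 are multicopy genes on the mouse X chromosome and Sly is their multicopy relative on the Y chromosome. The series asked how lowering each family changes gene expression in spermatids relative to matched controls. Normalized log2 signals correlated at 0.973 or more between any 2 arrays across 16572 probes. The 2 deposited tables disagree over the identity of 6 of the 8 columns, so each direction below holds for the arrays as labelled by sample accession.

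**Figure D1:**
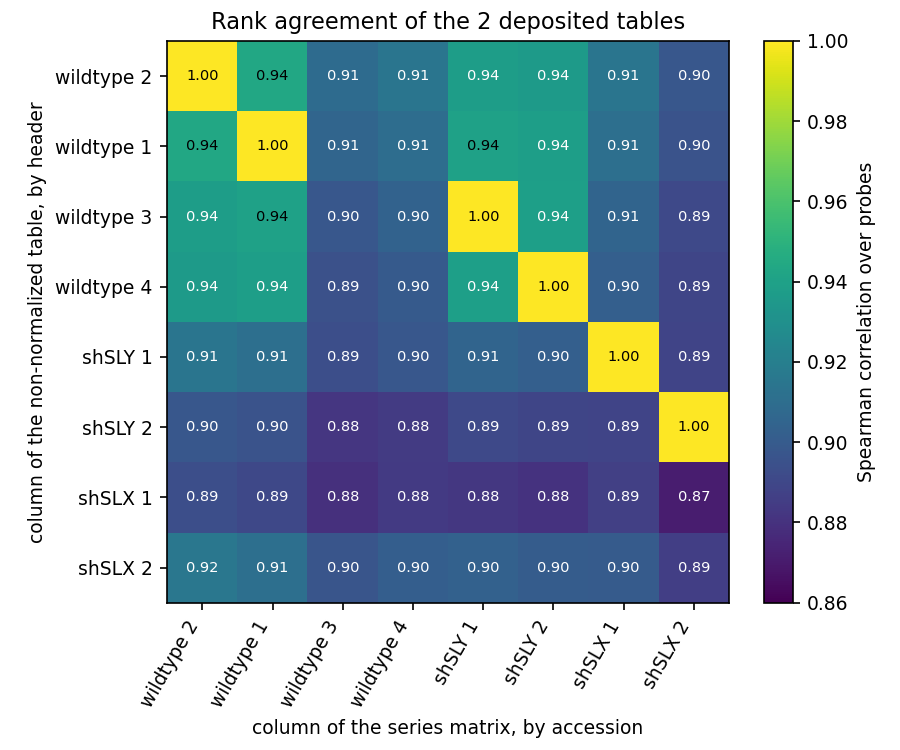
Spearman correlation over 45281 probes between each column of the non-normalized table (rows, by header) and each column of the series matrix (columns, by accession). A value of 1 on the diagonal appears for wildtype 1 and 2, values of 1 off the diagonal join 4 further columns to other samples, and the last 2 rows reach at most 0.916.

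The targeted transcripts were examined first. Sly was measured by 1 probe, and no probe carried the name Slx or Slxl1. In the arrays labelled shSLX, Sly fell by 0.86 ± 0.17 (SE) on the log2 scale, or 1.82-fold, with a limma adjusted p of 0.0377. The log2 signals were 9.45 and 8.93 in the 2 shSLX arrays against 10.05 and 10.04 in wildtype 3 and 4 on the same slide. Sly in the arrays labelled shSLY differed from wildtype by -0.11 ± 0.21 and did not pass the test (adjusted p = 0.959), with signals of 10.56 and 10.26 against 10.52 in wildtype 1. A fall of Sly against wildtype, which the shSLY label would predict, was thus not seen. The other Y genes rose in those arrays, however (median 0.57), and Sly lay 0.68 below them. Sly therefore does not settle the labels, and the directions given for the arrays labelled shSLY and shSLX should be read with this doubt. The difference between the 2 effects on Sly was not past the threshold (-0.75, adjusted p = 0.257). The fall in the arrays labelled shSLX lost its call when the slide was fitted alone (adjusted p = 0.0597) or with offset 16 (0.0601). It also lost it without wildtype 3 or wildtype 4 (0.319 and 0.317), and without either shSLY array (0.0597). The log2 fold change was then -0.85 without wildtype 3, -0.87 without wildtype 4 and -0.86 without either shSLY array.

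Sly had the lowest log2 fold change of the 16 measured Y genes in both comparisons. In the arrays labelled shSLY it was the 1 Y gene below 0, and it lay 0.68 below the median of the other Y genes (0.57). In the arrays labelled shSLX it lay 0.77 below the median of the others (-0.089). Sly is a multicopy gene, and near-identical family members can bind the same probe.

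**Figure D2:**
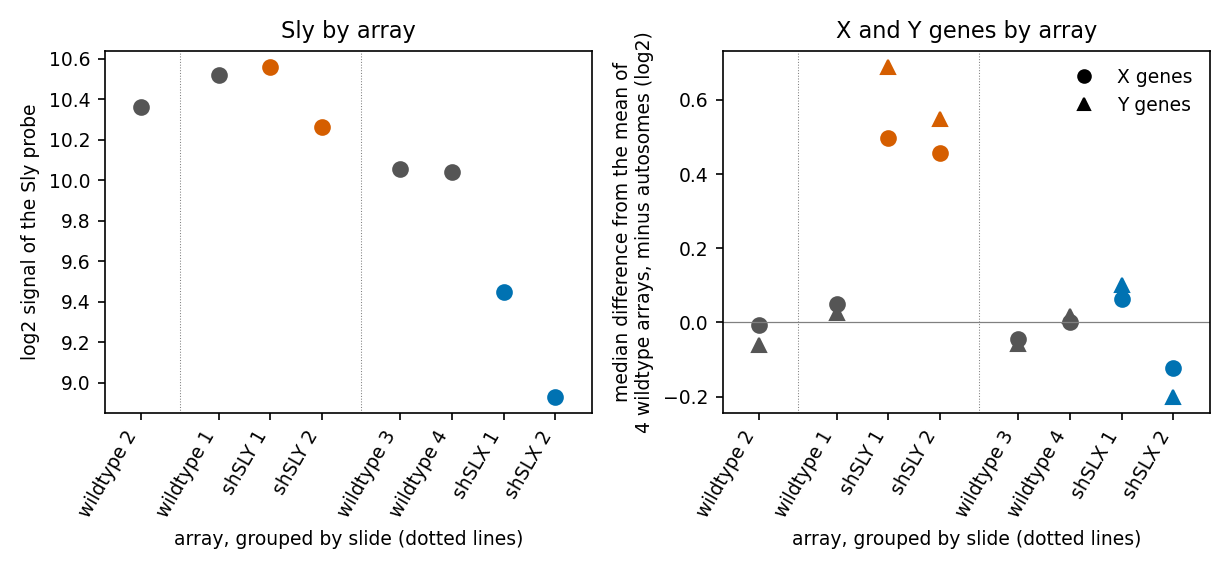
Left, log2 signal of the Sly probe on each array; right, median difference of X genes (circles) and Y genes (triangles) from the mean of the 4 wildtype arrays, less the autosomal median, on the log2 scale. Arrays are grouped by slide, each point is 1 array, and the X medians of the arrays labelled shSLY (0.50 and 0.46) lie above those of all other arrays, the highest of which is 0.06.

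Genes of both sex chromosomes were broadly higher in the arrays labelled shSLY. Of 263 X genes, 93.5% had a log2 fold change above 0 and the median was 0.43, against -0.017 for 9137 autosomal genes. Of 16 Y genes, 15 lay above 0 and the median was 0.51. After adjustment over all probes, 31 X genes and 5 Y genes rose and no X or Y gene fell. Adjusted over the list alone, 128 X genes and 11 Y genes rose. Camera gave an adjusted p of 1.11e-59 for X and 7.98e-16 for Y. With an estimated correlation the adjusted p was 0.0528 for X and 0.0966 for Y, so neither call held. Fry, which does not set these genes against the others, gave an unadjusted p of 0.015 for X and 0.039 for Y. None of the 10000 matched random autosomal lists reached either median. Against wildtype 1 on their own slide, the 2 arrays gave X shifts of 0.45 and 0.43 and Y shifts of 0.62 and 0.45.

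**Figure D3:**
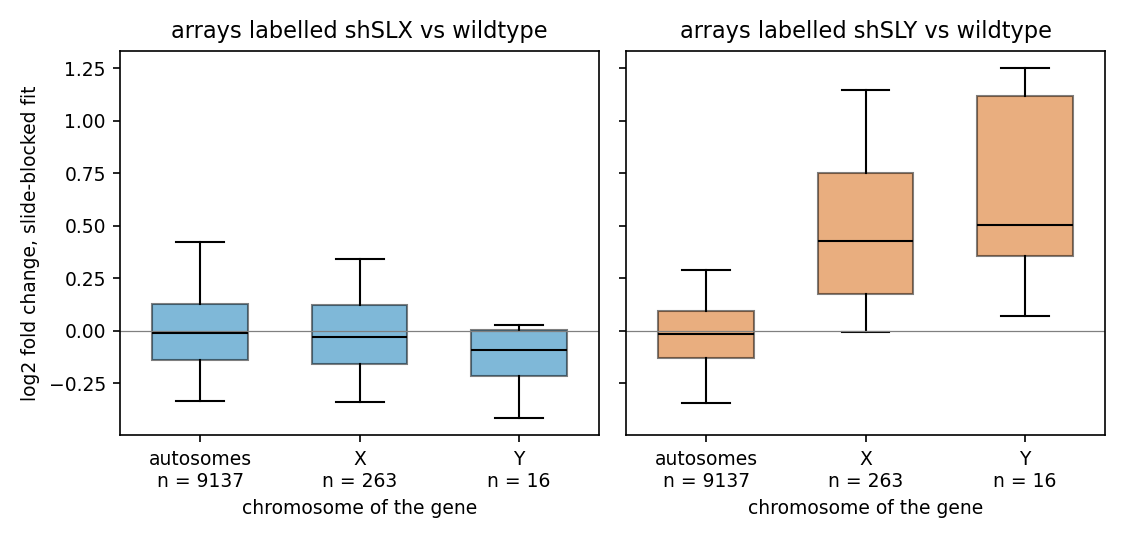
Log2 fold changes against wildtype, 1 probe per gene, for 9137 autosomal, 263 X and 16 Y genes in the arrays labelled shSLX (left) and shSLY (right). Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles; in the arrays labelled shSLY the X and Y medians are 0.43 and 0.51.

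Among named genes, the 12 largest rises taken by the naming rule in the arrays labelled shSLY were all X- or Y-linked. Unnamed probes, 46 of those past the threshold, have no chromosome here, and some rose by more. Rhox11, a homeobox gene, rose by 1.60 ± 0.21 on the log2 scale (3.04-fold, adjusted p = 0.0216). Gm15104 and Actrt1, an actin-related gene of the testis, each rose by 1.46 to 1.47. Asb12 rose by 1.42 ± 0.13 with an adjusted p of 0.00537, and Tgif2lx1, a homeobox gene expressed in testis, by 1.37 ± 0.16. Further X-linked rises were Cypt15 (1.36), Cypt2 (1.27), Cldn34c1 (1.27), Gm14725 (1.25) and Zcchc13 (1.23, with both of its probes past the threshold). On the Y, Gm20738 rose by 1.26 and Ssty1, a spermatid-specific spindlin relative, by 1.25 ± 0.20. By probe, 35 of the 55 rises with a known chromosome were on X, against 348 X probes tested (two-sided Fisher's exact test, p = 6.48e-43). That test treats probes as independent, but some share a gene and X genes were correlated (estimated at 0.22). Its p-value therefore overstates the evidence. No X or Y probe was among the 16 falls with a known chromosome.

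Falls in the arrays labelled shSLY were autosomal or on no placed chromosome. Fndc3a, a gene needed for spermatid adhesion to Sertoli cells, fell by 1.71 ± 0.12 (3.27-fold, adjusted p = 0.00196). The angiotensin receptor gene Agtr1a fell by 1.43 ± 0.20, and Btrc, which encodes a ubiquitin ligase subunit, by 1.15 ± 0.12. Esrrb, Gm5409 and Rnf170 fell by 1.10, 1.08 and 1.07, the last with both probes past the threshold. Rdm1, Gm9748, Cobll1, Rplp1, Sdr39u1 and Rpp21 fell by 0.94 to 0.85. For Btrc and Cobll1, 1 of 2 probes passed. Rplp1 and Rpp21 encode a ribosomal protein and a subunit of RNase P. Fndc3a and Rnf170 are examined again below, since both rose in the arrays labelled shSLX.

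In all, 96 probes rose and 22 fell in the arrays labelled shSLY (limma, adjusted p under 0.05), and 1477 probes had an unadjusted p under 0.05. The count rose to 635 with no slide term, 469 with the slide as a random block and 558 on that slide alone, and fell to 17 with offset 16 and 45 with 1 probe per gene. It was 5 without wildtype 3, 5 without wildtype 4, 18 without shSLY 1, 12 without shSLY 2 and 516 without either shSLX array. The split was 421 rises and 214 falls with no slide term, 328 and 141 with the random block, 350 and 208 on that slide alone, 328 and 188 without either shSLX array, 11 and 6 with offset 16, 34 and 11 with 1 probe per gene, and 2 and 3 without wildtype 3 or without wildtype 4. Under the headers of the non-normalized table, 50 probes changed (44 rises and 6 falls), 1 of them shared, and the X and Y shifts over autosomal genes turned to -0.13 and -0.071, of which X passed camera's test as lower.

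Among the lists, the 18 measured members of the X multicopy spermatid list all lay above 0, with a median of 0.73. By 1 probe per gene and after adjustment over all probes, 3 rose, Cypt2, Cypt15 and Tcp11x2 (1.14 ± 0.20), and 15 rose adjusted over the list alone. Of 9 Y-linked genes, 2 rose, Ssty2 (1.11 ± 0.16) and Ssty1, and 5 adjusted over the list alone. The autosomal multicopy Speer and takusan genes had a median of 0.36 over 9 members. None passed over all probes, Speer4cos and Speer4d were at 0.55 and 0.65, and 4 rose adjusted over the list alone. Camera adjusted p-values for these lists were 3.32e-20, 9.98e-06 and 8.57e-04, and each was 0.914 with an estimated correlation. Unadjusted p-values from fry were 0.037, 0.072 and 0.125 in the same order. None of the 3 passed under the headers of the non-normalized table. The acrosome list had a median of -0.053 over 30 genes, 1 of which rose, the X-linked Spaca5 (1.12 ± 0.14). It was not past the threshold as a list.

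No other list passed in the arrays labelled shSLY. Of 33 sperm tail genes, 15 lay above 0, and sperm chromatin genes had a median of 0.019 over 21, spermatid regulators -0.024 over 22 and meiotic genes 0.093 over 20. Markers of other testis cells were at a median of 0.115 for Sertoli cells, 0.28 for 2 Leydig genes, 0.016 for stroma, 0.025 for immune cells and 0.055 for spermatogonia. With no slide term, the immune list (0.57, adjusted p = 0.017) and the Sertoli list (0.32, adjusted p = 0.0218) passed as higher. The Sertoli list also passed without shSLY 1 (0.25, adjusted p = 0.0242). Under the headers of the non-normalized table, the Sertoli (-0.62) and immune (-0.42) lists passed as lower and the stromal list (0.46) as higher. Medians of the apoptosis, stress, interferon, heterochromatin, small RNA, ubiquitin, ribosomal, mitochondrial and Xlr family lists lay between -0.086 and 0.12, with camera adjusted p of 0.586 or more. By the 1 probe per gene used for lists, Rplp1 was the 1 member of these lists past the threshold. Another probe of Bcl2l1, of the apoptosis list and chosen after its values were seen, rose by 0.74 ± 0.13, while the probe used was at 0.14.

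**Figure D4:**
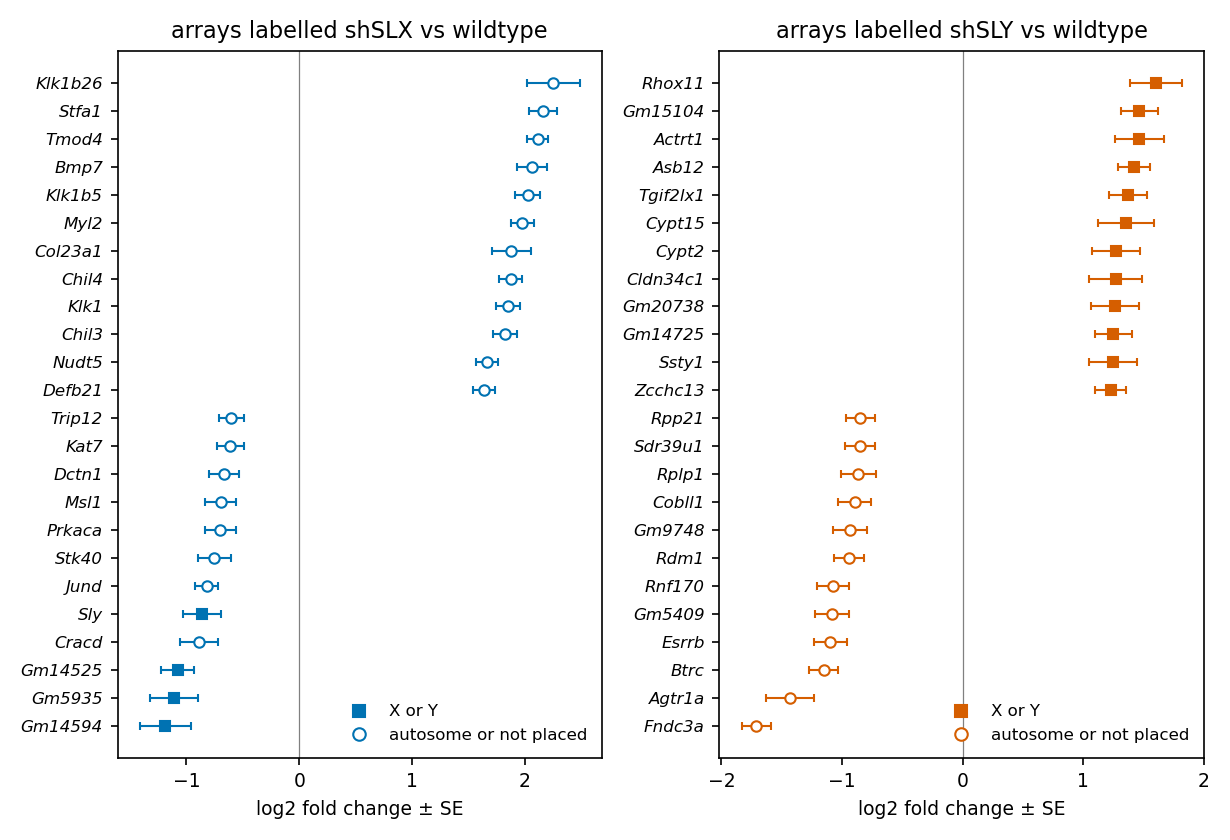
Log2 fold change ± SE of the genes with the largest rises and falls past the threshold in the arrays labelled shSLX (left, set against 2 wildtype arrays) and shSLY (right, set against 1). Filled squares are X or Y genes and open circles are autosomal or unplaced genes. The 12 rises on the right are all squares and the 12 on the left are all circles, as are most tested probes with a known chromosome (13443 autosomal, 348 X and 16 Y).

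The largest changes in the arrays labelled shSLX were rises of autosomal genes. Tissue kallikrein genes, which encode serine proteases, were among them: Klk1b26 rose by 2.25 ± 0.24, Klk1b5 by 2.02 ± 0.11 and Klk1 by 1.85 ± 0.10 on the log2 scale. Stfa1, a cysteine protease inhibitor, rose by 2.16 ± 0.12 (4.47-fold, adjusted p = 8.56e-05). The muscle genes Tmod4 and Myl2 rose by 2.11 ± 0.10 and 1.98 ± 0.10, with all 3 Tmod4 probes past the threshold. The growth factor gene Bmp7 rose by 2.06 ± 0.13 and the collagen gene Col23a1 by 1.88 ± 0.17. Chil4 and Chil3, chitinase-like genes, rose by 1.87 and 1.82, Nudt5 by 1.67 and the beta-defensin gene Defb21 by 1.64. For Klk1b26 and Nudt5, 1 of 2 probes passed.

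The largest falls in the arrays labelled shSLX were of 3 X genes, Gm14594 (-1.19 ± 0.23), Gm5935 (-1.11 ± 0.21) and Gm14525 (-1.08 ± 0.15). In the order of protein-coding genes of the GRCm38.p6 annotation, Gm14525 is 1 place from Slx, Gm5935 is 8 places from Slx and Gm14594 is 7 places from Slxl1. Slx and Slxl1 are multicopy, and whether these 3 genes are copies of them was not examined. With shSLY these genes were at 0.67, 0.41 and 0.93 in the same order, none past the threshold. Cracd fell by 0.89 ± 0.17, with another of its probes on the other side of 0, and the AP-1 gene Jund by 0.82 ± 0.10. Stk40, Prkaca, Msl1, Dctn1, Kat7 and Trip12 fell by 0.75 to 0.60. For Stk40, Prkaca, Msl1 and Kat7, 1 of 2 probes passed, and for Trip12 2 of 4. Prkaca encodes a catalytic subunit of protein kinase A, and Msl1 and Kat7 encode chromatin proteins.

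Unlike the arrays labelled shSLY, those labelled shSLX had no shift of the sex chromosomes past the threshold. The X median was -0.028 and the Y median -0.092, with camera adjusted p of 0.358 and 0.174. The 2 arrays lay on either side of 0, with X shifts of 0.081 and -0.11 against their own slide. With shSLX 1 left out, X (-0.11) and Y (-0.26) genes passed camera's test as lower, and with shSLX 2 left out X genes (0.081) passed it as higher. Under the headers of the non-normalized table, X (-0.73) and Y (-0.90) genes both passed as lower. There, the columns headed wildtype on the shSLX slide hold the ranks of shSLY 1 and 2, whose X and Y rise would enter as a fall. Of 263 X genes, 1 rose and 3 fell.

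In all, 363 probes rose and 37 fell in the arrays labelled shSLX (limma, adjusted p under 0.05), and 2849 had an unadjusted p under 0.05. The count was 51 without wildtype 3, 43 without wildtype 4, 613 without shSLX 1, 2495 without shSLX 2 and 250 without either shSLY array or on that slide alone. No probe fell without wildtype 3 or 4, while 482 rose and 131 fell without shSLX 1, and 1167 rose and 1328 fell without shSLX 2. The count was 266 with probes detected in all 8 columns. Under the headers of the non-normalized table it was 2683 (1344 rises and 1339 falls), of which 106 were shared. There, Klk1, Klk1b5, Klk1b26, Bmp7, Myl2 and Col23a1 had negative fold changes.

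Of the 22 lists, those of stromal and immune cells were past the threshold as higher in the arrays labelled shSLX (camera adjusted p = 1.23e-04 and 3.52e-04). With an estimated correlation neither passed (adjusted p = 0.656 for each). Unadjusted p-values from fry were 0.0057 and 0.014, and those of the sperm chromatin (0.010) and ubiquitin (0.022) lists were also under 0.05. All 7 measured stromal and peritubular genes lay above 0, with a median of 0.52. After adjustment over all probes 3 rose, Dcn (1.18 ± 0.12), Acta2 (0.82 ± 0.12) and Myh11 (0.78 ± 0.11), and 4 adjusted over the list alone. Decorin is a matrix proteoglycan and the other 2 encode smooth muscle actin and myosin. Acta2 had 1 of 3 probes past the threshold. Of 7 immune genes, 6 lay above 0, with a median of 0.35. The lysozyme genes Lyz1 (1.24 ± 0.15) and Lyz2 (0.95 ± 0.16) and the complement gene C1qc (0.56 ± 0.11) rose, and 5 rose adjusted over the list alone. Lyz1 and Lyz2 each had 1 of 2 probes past the threshold. Against wildtype on their own slide, the 2 arrays gave stromal medians of 0.32 and 0.71 and immune medians of 0.61 and 0.29. The immune call was lost with no slide term (adjusted p = 0.715) and with the slide as a random block (0.605). The stromal call was lost without the slide term and shSLX 2 (0.37). Under the headers of the non-normalized table, the stromal list lost its rise (0.016) and the immune list passed as lower (-0.77, camera adjusted p = 0.0272). Against all 4 wildtype arrays, the immune medians of the 2 shSLX arrays (0.21 and 0.095) lay within the wildtype range of -0.36 to 0.53 and below those of the shSLY arrays (0.53 and 0.60).

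No other list passed in the arrays labelled shSLX. Sertoli markers had a median of -0.16, with 1 of 9 above 0. That list passed as lower with no slide term (-0.26, adjusted p = 0.0268) and under the headers of the non-normalized table (-0.75, adjusted p = 0.0271). The 2 Leydig genes had a median of -0.079 with Insl3 at -0.10. By 1 probe per gene, single members rose in 3 lists: Sohlh1, a transcription factor of spermatogonia (0.73 ± 0.11), Gadd45g, a stress gene of the apoptosis list (0.70 ± 0.11), and H2al2a, a histone variant of condensing spermatids (0.61 ± 0.10). Sperm chromatin genes had a median of 0.035, with 4 rising and 2 falling adjusted over the list alone. The acrosome median was -0.041, the sperm tail median -0.021, the meiotic median -0.0060 and the X multicopy median 0.092. In these 4 lists no member passed. The remaining lists, from spermatid regulators to ribosomal proteins, had medians between -0.15 and 0.17 and camera adjusted p of 0.303 or more. Of these, spermatogonia passed as higher without wildtype 4 (0.35, adjusted p = 0.0157). The X multicopy list passed as higher without shSLX 2 (0.21, adjusted p = 0.00361) and as lower without the slide term and shSLX 1 (-0.14, adjusted p = 0.0158). Another probe of Drosha, of the small RNA list and also chosen after its values were seen, rose by 0.53.

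The effects of the 2 transgenes were then compared directly. In limma's test of the difference, 298 probes differed, 194 higher and 104 lower in the shSLX effect relative to the shSLY effect, and 2271 had an unadjusted p under 0.05. Among named genes Fndc3a led, while the unnamed probe ILMN_2476405, chosen after its values were seen, differed by more (-5.97). Fndc3a rose by 1.32 in the arrays labelled shSLX and fell by 1.71 in those labelled shSLY, a difference of 3.03 ± 0.16 (adjusted p = 1.65e-04). The next 5 genes were Tmod4 (2.55), Chil3 (2.33), Chil4 (2.23), Defb21 (2.13) and Strn (1.96). The X median differed by -0.44 and the Y median by -0.76, with camera adjusted p of 1.16e-30 and 2.19e-11. With an estimated correlation the adjusted p was 0.126 and 0.141. The count was 2445 with no slide term (1187 higher and 1258 lower), 1043 with a random slide block (565 higher and 478 lower), 171 with offset 16 and 175 with 1 probe per gene. Leaving out 1 array under the slide block gave 14 without wildtype 3 (13 higher and 1 lower), 13 without wildtype 4 (11 higher and 2 lower), 44 and 32 without shSLY 1 and 2, and 793 and 1695 without shSLX 1 and 2, the last with 879 higher and 816 lower. Under the headers of the non-normalized table it was 21 (3 higher and 18 lower).

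The 2 sets of fold changes were nearly uncorrelated across probes, which are not independent replicates (Pearson -0.038, Spearman -0.037). Unchanged groups simulated on the same design gave Pearson values from -0.026 to 0.030, and the covariance was -0.00218 against a simulated covariance of -5.98e-06. With the slide term the comparisons use different wildtype arrays. With no slide term they share all 4, and the Pearson correlation was -0.15 against a simulated 0.33. The simulation held no differences between slides, which enter the comparisons when the slide term is left out. The 2 values therefore cannot be set against each other, and no conclusion is drawn from them. Of 363 and 96 rises, 4 were shared, against 2.10 for independent lists. No fall was shared, and 3 probes of Fndc3a and Rnf170 rose with shSLX and fell with shSLY, against 0.48 for independent lists. An unnamed probe was the 1 that fell with shSLX and rose with shSLY, against 0.214.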

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

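Except for the stromal and macrophage gene sets listed before their values were looked at, the tests of explanations were chosen after the results were seen.

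The wildtype arrays were checked for single values far from the other 3, over 120 sets of 4 values, of which about 5% would stand apart by chance. Col23a1 stood apart in wildtype 1, at a log2 signal of 8.17 against 7.90 to 7.92. Rhox11 stood apart in wildtype 4, at 7.85 against 7.75 to 7.77.

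The effects of the 2 transgenes differed for 298 probes. Among gene groups, the median difference (shSLX effect minus shSLY effect, log2) was -0.44 for X genes, -0.76 for Y genes, -0.66 for the X multicopy list, -0.38 for the Y-linked list and -0.28 for Sertoli markers. It was 0.69 for the stromal list and 0.52 for the immune list. With an estimated correlation none of these passed. Of 116 named genes, 40 differed. Those lower in the shSLX effect were Gm14594 (-2.12), Rhox11 (-1.79), Gm14525 (-1.75), Gm15104 (-1.68), Gm14725 (-1.63), Actrt1 (-1.61), Cldn34c1 (-1.48), Gm20738 (-1.41), Cypt2 (-1.39), Ssty1 (-1.36), Asb12 (-1.29), Tgif2lx1 (-1.23), Jund (-1.21), Zcchc13 (-1.16), Spaca5 (-1.13) and Ssty2 (-1.10). Those moderately higher were H2al2a (0.79), Rpp21 (0.80), Rdm1 (0.88), Gm5409 (0.95), Btrc (0.96), Cobll1 (0.98), Rnf148 (1.02), Dcn (1.02), Rplp1 (1.06), Esrrb (1.14), Lyz1 (1.14) and Klk1b5 (1.20). Those further apart were Klk1 (1.37), Nudt5 (1.39), Bmp7 (1.70), Myl2 (1.81), Rnf170 (1.89), Strn (1.96), Defb21 (2.13), Stfa1 (2.20), Chil4 (2.23), Chil3 (2.29 and 2.33), Tmod4 (2.37 and 2.55) and Fndc3a (3.03).

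The first pattern weighed was the rise of X and Y genes in the arrays labelled shSLY. An additive difference between slides cancels in the fit, which sets these arrays against wildtype 1 on their slide (X shifts of 0.45 and 0.43). Without the slide term, such a difference is argued against by wildtype 1, which lay only 0.065 above the other wildtype arrays on X. Both points rest on 1 wildtype array and on the slide labels, which are disputed as described above. A larger share of round spermatids would raise autosomal spermatid genes as much only if these are confined to round spermatids, which was not tested. The 82 autosomal genes of the acrosome, chromatin and tail lists had a median of -0.018 with an interquartile range of 0.13, against 0.43 for X. These values argue only against a change in cell share that would raise those genes too, and another change in share stays open. By Sly, arrays under the wrong label cannot be told apart from the labelled effect. Sly lay 0.68 below the median of the other Y genes (-0.68), but it was also the lowest Y gene in the arrays labelled shSLX. Gm14525, Gm5935 and Gm14594, near Slx or Slxl1, were lower with shSLX and not with shSLY. They were picked as the largest falls with shSLX, so they do not settle the labels. An effect of the transgene against Sly on sex-linked transcription stays a hypothesis, untested beyond these arrays.

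The second pattern was the higher level of the stromal and immune lists in the arrays labelled shSLX. A general loss of purity, with all somatic cells in place of germ cells, is argued against by Sertoli markers, whose median of -0.16 lay 0.67 below the stromal median, more than the interquartile range of either list, and which was lower still with no slide term (-0.26). Macrophages carried along may account for the immune part, but low controls cannot be told apart from this. The 6 further macrophage genes measured all lay above 0, with a median of 0.33 (camera p = 0.00326, and p = 0.0975 with an estimated correlation). They were led by Ctsb (0.60), the 1 past the threshold, and Lgmn (0.45), and the median in the arrays labelled shSLY was 0.13. The controls here were wildtype 3 and 4, whose immune medians against all 4 wildtype arrays were low (-0.36 and -0.26). Carried-over stromal cells stay open, because only 3 of 9 further stromal genes were measured, with a median of 0.075, Mgp at 0.73 and Myl9 at -0.093, against a median of 0.35 in the arrays labelled shSLY, which passed camera's test at the preset correlation alone, and where the stromal list itself was at 0.016. A change in expression within germ cells stays open as well.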

How the results depend on the processing

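The offset of 16, the 2 other filters and the exchange of tables were added after the data had been seen, and causes were not tested except where stated. The X and Y shifts in the arrays labelled shSLY kept their direction and their call with every setting fitted to the series matrix at the preset correlation, but not with the non-normalized table, the source first planned, whose values are given further on. Named genes kept their sign and call without background correction, with median centring and with no filter. Median centring could change little, because the authors had already normalized the values, and that normalization was not varied. With an estimated correlation the X shift had p = 0.0264 (adjusted 0.0528), the Y shift (0.52) p = 0.0966, and 0 lists passed in either comparison. With no slide term, 635 probes changed with shSLY, 2445 differed, 5 lists passed with shSLY, immune (0.57) and Sertoli (0.32) among them, and the correlation of effects was -0.15. With a random slide block these were 469, 1043 and, for shSLX, 1 list. On a single slide, 250 probes changed with shSLX and 558 with shSLY, and Sly (-0.86) lost its call. With offset 16, 17 changed with shSLY, 171 differed and Sly (-0.90) lost its call. With 1 probe per gene, which tests fewer probes, 45 changed with shSLY and 175 differed. With detection in all 8 columns, 266 changed with shSLX.

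The replicate numbers were also fitted as a replicate block in place of the slide, leaving 2 residual degrees of freedom: 2103 probes changed with shSLX, 334 with shSLY and 4383 differed, and the X shift with shSLX was -0.064 and passed. The Sertoli list passed as lower with shSLX (-0.39). The Speer and takusan list (-0.41) and Speer4d (-0.86) turned and passed as lower with shSLX, and C1qc (-0.043) and the immune list (-0.10) turned without passing. Same-numbered samples deviated together in 2 of 6 pairs, at 0.14 (wildtype 1 and shSLX 1) and 0.22 (wildtype 2 and shSLY 2), against -0.084 to -0.063 in the others. Deviations were taken from the group mean, so 2 arrays of a group mirror each other. The 2 pairs of shSLX with shSLY thus gave 1 value (-0.063), and the 6 pairs are not separate. Wildtype 1 with 2 was at 0.49 and with 3 at -0.75, which gives no scale for pairing. Same-numbered samples share only a number.

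Under the headers of the non-normalized table, where 4 columns hold other samples' ranks, 2683 probes changed with shSLX, 50 with shSLY and 21 differed, 5 lists passed with shSLX, and effects correlated at 0.53. The columns headed wildtype 3 and 4 hold the ranks of shSLY 1 and 2, and those headed shSLY the ranks of shSLX 1 and 2. The values below therefore partly repeat the contrasts by accession under exchanged names, and a turned sign is no separate evidence. X and Y shifts were -0.73 and -0.90 with shSLX, both passing as lower, and -0.13 and -0.071 with shSLY, of which X passed as lower. With shSLX the sign turned for Klk1b26 (-1.90), Bmp7 (-1.81), Klk1b5 (-1.68), Klk1 (-1.41), Speer4cos (-1.38), C1qc (-1.16), Speer4d (-1.06), Lyz1 (-0.95), H2al1n (-0.90), Col23a1 (-0.86), Myl2 (-0.78), Lyz2 (-0.77), Gadd45g (-0.62), Sohlh1 (-0.50), Myh11 (-0.46) and Acta2 (-0.15). It also turned for the Speer and takusan (-0.94), X multicopy (-0.85) and immune (-0.77) lists, each of which passed as lower. With shSLY it turned for Gm14725 (-0.66), Cypt15 (-0.55), Cypt2 (-0.51), Spaca5 (-0.46), Gm15104 (-0.42), Ssty1 (-0.33), Cldn34c1 (-0.23), Actrt1 (-0.20), Rhox11 (-0.19), Gm20738 (-0.083), Gm5409 (0.044), Agtr1a (0.17), Gm9748 (0.30), Cobll1 (0.31), Rnf170 (0.82) and Fndc3a (1.27). The Sertoli (-0.62) and immune (-0.42) lists turned and passed as lower, the Speer and takusan list (-0.61) turned without passing, and the stromal list (0.46) passed as higher.

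Each array was left out in turn, with and without the slide term. A lone array is then assumed to vary like the other groups, and without wildtype 1 the shSLY effect could not be estimated under the slide block. Under that block each fold change rests only on the arrays of its own slide. Leaving out an array of another slide could change its p-value but not its value. The X shifts of 0.43 to 0.45 with shSLY under that block are each shSLY array alone against wildtype 1, so their narrow range is no measure of stability. Counts ranged from 43 to 2495 for shSLX, 5 to 669 for shSLY and 13 to 2635 for the difference. The X shift ranged from -0.12 to 0.081 for shSLX and 0.43 to 0.50 for shSLY, the Y shift from -0.26 to 0.10 and 0.45 to 0.69. Sly ranged from -1.31 to -0.60 and -0.26 to 0.31. Lists passing ranged from 1 to 3 and 3 to 6, and the correlation of effects from -0.19 to 0.014. Over the lists and named genes, leaving out 1 array ended the call in 299 results, brought one in 63 and turned the sign of a value called in either fit in 1. In 2241 the call did not change, although values with no call also changed sign. The other settings gave 100, 24, 42 and 1820. Under the slide block, leaving out wildtype 2 could not change any result, because that array is alone on its slide. Its results are among the 2241. With no slide term and without shSLX 1, the X multicopy list passed as lower with shSLX (-0.14), and without shSLX 2 it passed as higher with the slide term (0.21) and with none (0.19). Spermatogonia passed as higher without wildtype 4 with shSLX (0.35) and, with no slide term, without wildtype 1 (0.28) or 2 (0.34) with shSLY. Signal over background limits dim probes, whose fold changes the offset of 50 shrinks.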

Other observations

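Except for the fixed gene lists, the groups and probes below were chosen after their values were seen.

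Kallikrein genes, singled out because several were among the largest rises, were higher in the arrays labelled shSLX. Of 11 probes for 7 genes of the Klk1 family, all lay above 0, with log2 fold changes from 0.57 to 2.25, and 10 probes covering all 7 genes passed the threshold. Probes of these close relatives can bind each other's transcripts and are not independent. In the arrays labelled shSLY, 3 probes of Klk1b5 and Klk1b9 also rose, by 0.77 to 0.82, and the family median was 0.61. Gm5168, 4 places from Slx in gene order, was at -1.07 ± 0.24 in the arrays labelled shSLX and did not pass (adjusted p = 0.0611). In those labelled shSLY it was at 0.60 and did not pass either.

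The X rise in the arrays labelled shSLY reached beyond the multicopy list: the 245 other X genes had a median of 0.40. The 131 X genes with the higher signals had a median of 0.73 and the other 132 a median of 0.21. Autosomal rises were few, with 15 probes past the threshold, among them Pex5 (1.13 ± 0.18), a peroxisomal import receptor gene whose 2 probes both rose, Eppin (0.97), a protease inhibitor gene of the male tract, and Btg4 (0.94). An unnamed probe, ILMN_2476405, rose by 6.03 ± 0.18 on the log2 scale in the arrays labelled shSLY (adjusted p = 2.89e-06). Its log2 signal was 12.2 ± 0.32 (SD) against 6.22 ± 0.07 in the 4 wildtype arrays, and its change in the arrays labelled shSLX was 0.06.

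The third pattern weighed was the disagreement of the 2 deposited tables. Raw background may follow the slide, and under the headers of the non-normalized table the raw medians of 1 slide ranged over 21.6 or 20.2 intensity units. Under the accession identities of the rank-matched columns they ranged over 2.58 and 9.23, which is consistent with headers out of place in the non-normalized table. It does not show that the accessions are right, and the 2 columns headed shSLX 1 and 2, with raw medians of 79.9 and 83.8, matched no accession. No biological explanation was tested.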
